A study of Sardinops sagax and Scomber japonicus with 20 samples.

How the data were processed

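Liver RNA was sequenced from 20 male fish of 2 species, the Pacific sardine (Sardinops sagax) and the chub mackerel (Scomber japonicus). In each species 5 fish were controls and 5 were kept for 5 h in seawater with 12.5 pM 17α-ethynylestradiol (EE2), the synthetic estrogen of contraceptive pills. Per the labels the water was at 17 °C, RNA had an integrity number of at least 7, and TruSeq libraries of about 300 bp were amplified over 10 PCR cycles. No paired analysis was possible because the labels give no replicate numbers that pair an exposed with a control fish, and they name no tank or sequencing batch.

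For each species 1 table was used, the result table of a DESeq2 comparison that the authors ran on the 2 groups. Per the file headers its values are the mean normalized count (a signal over all libraries of the fit), the log2 fold change with its standard error (both in log2), the Wald statistic (a score) and the p-value, raw and adjusted. Per the labels the authors used CASAVA 1.8, DESeq2 and the zebrafish build GRCz10; the aligner, the counting tool, the filters and the DESeq2 version are not given in the sources used here. The deposited sardine rows carry names of zebrafish RefSeq transcripts, either curated records or records predicted from the genome, and the deposited mackerel rows carry numbers of fugu gene models. Both tables add a human gene symbol per row, which is the symbol printed here, and neither holds coordinates in a fish genome. Neither table holds values per fish, so the total count of each library is unknown.

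The tables do not record which group is the numerator of the fold change. Values are therefore described as higher on the positive side or higher on the negative side, and no change is assigned to exposure. With the default order of groups in the authors' software the positive side would be the exposed group. Each comparison is named control versus exposed, which can be read the other way, with control as the numerator. Which order the authors used is not stated. A row is called when its adjusted p in the authors' deposited table is under 0.05.

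The mean normalized counts fell on a regular grid, from which whole numbers behind them were recovered. In mackerel each mean was 0.455 times a whole number for the positive side plus 0.563 times a whole number for the negative side plus a constant of 1.66. All 9191 rows had a solution, with a largest residual of 3.34e-06 counts. Where several pairs of whole numbers fitted a mean, the pair nearest the row's fold change was taken, and 0 rows had more than 1 pair near it. When the means were shifted off the grid, 0.0979% of rows had a solution. In sardine 6 whole numbers were needed, 5 for the positive side and 1 for the negative side, and 5120 of the 5123 rows with a mean of at most 5 had a single solution, against 0.0586% of shifted rows. For the more abundant sardine rows the negative-side number was estimated from the mean and the fold change. These numbers are called recovered reads. The mackerel rows summed to 376343 recovered reads on the positive side and 332486 on the negative side, and the sardine negative side to an estimated 125418. On the solved sardine rows alone the negative side held 7284 reads and the 5 positive-side libraries 9038, 10162, 6449, 5558 and 5768. Recovery was tested on simulated tables, in which the whole numbers of 100% of 9191 mackerel and 5057 sardine rows were found again. The simulated mackerel fold changes followed the formula that also chose among several fitting pairs. The simulation therefore could not show errors of that choice in the authors' fold changes.

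Because no values per fish were at hand, no test between fish was run, no interaction between species was tested, and the authors' adjusted p is the test reported. For mackerel the 2 recovered reads of a row were also compared with an exact two-sided binomial test against the positive-side share expected from the grid (55.3%), with Benjamini-Hochberg adjustment over all rows; ratios carry the exact 95% interval of that test. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only, and the exact test compares 2 totals, not 2 sets of fish. In 200 simulated rows changed 4-fold the exact test called 37, and 27 of the 28 with at least 50 reads; it called 1 unchanged row. Where a side had 0 reads, the fold is a lower bound against a floor of 3 counts over that side.

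The 28 gene lists, the rule for named genes and the threshold were fixed before the data were examined. Rows were matched to lists by symbol, with a final a or b ignored in list names and in the human symbols of the rows, so that some paralogues were included (ARPC1A and CORO1B among the leukocyte markers, TOP2B in the cell cycle). For each list of at least 3 rows, members called on each side were counted, over all genes and adjusted over the list alone by the Benjamini-Hochberg method. The median fold change of a list was placed among those of 10000 random lists matched on 20 abundance bins (seed 1), and a list was called displaced outside the central 95%. Among 100 simulated lists of 25 rows shifted by 1 log2 unit this measure found 14 in sardine and 100 in mackerel, and among 100 unshifted lists 3 and 4. Neither the random nor the simulated lists hold the correlation between genes of a real list, so the rate of false displacement is unknown. No correction was made over the 28 lists. The measure was not among the planned tests of gene lists, which needed values per library. The lists for cardiac muscle and for fast skeletal muscle were added after the sardine table had been seen. Named genes were the measured egg proteins and hormone genes, the 10 called rows with the largest fold change on each side with an average log2 CPM of at least 1, up to 4 called members of each list with the smallest p, and the 10 genes called in both species with the smallest larger p; some genes that this rule names are not reported here. Between species, Pearson's r and Spearman's rho were computed across the most abundant row per shared symbol, beside 1000 random pairings.

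The alternatives set beforehand that the tables allowed were an adjusted p under 0.1, Benjamini-Hochberg adjustment recomputed from the p-values, a fold of at least 2, lists without the 10 most abundant rows, and shared symbols with an average log2 CPM of at least 3. Alternatives added after seeing the data were curated records only, rows with reads on both sides, a mean of at least 10, at least 10 recovered reads, a single row per symbol, the mean of a symbol's rows, the rows without the muscle lists, lists without such paralogues, and the exact test. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.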

Results

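The data were 1 result table per species from liver RNA sequencing, each comparing 5 fish exposed to EE2 for 5 h with 5 controls. The sardine table held 6716 rows with 5423 gene symbols and that of the mackerel 9191 rows with 7400 symbols. Depth per library is unknown; a mackerel row rested on a median of 4 recovered reads over both sides, and the median mean normalized count was 1.43 in sardine and 3.48 in mackerel. The 10 most abundant rows held 33.1% of the mean normalized counts in sardine and 32.9% in mackerel. Values per fish were not at hand, so the error given is the standard error (SE) of the authors' deposited table, and the tables do not record which group the positive side is.

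The first comparison asked which liver transcripts differ between exposed and control sardines. In the authors' deposited table muscle genes were far higher on the negative side: the thin-filament gene TPM3 in its most abundant row had a log2 fold change of -9.17 ± 0.27 (SE; adjusted p 2.4e-246), cardiac troponin TNNT2 -11.17 ± 0.93 and the cardiac myosin MYH6 -10.36 ± 0.94. Genes for blood proteins that hepatocytes secrete were higher on the positive side, with fibrinogen FGG at 2.38 ± 0.10 (adjusted p 6.86e-124), prothrombin F2 at 2.02 ± 0.11, complement C3 at 4.97 ± 0.48 and the protease inhibitor SERPINA1 at 2.78 ± 0.31 in the authors' deposited table. The sterol synthesis genes IDI1 (2.54 ± 0.35), DHCR7 (3.0 ± 0.46) and LSS (3.09 ± 0.47) were also higher there. In all, 3071 of 6600 rows with an adjusted p were called by the authors' DESeq2 test, 2010 on the positive and 1061 on the negative side, at a median of -0.19 over all rows.

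The 10 sardine rows with the largest negative fold change all carried genes known from muscle. A second TPM3 row was at 0 on the positive side and at least 796-fold lower there. Slow troponin TNNI1 was at least 714-fold, the muscle filament gene DES at least 564-fold, and the myosin MYH7 at least 307-fold lower. The atrial light chain MYL7 was at least 266-fold and troponin TNNC1 at least 236-fold lower on the positive side, with 0 reads there. MYL4 had a fold change of -10.69 ± 1.2 in the authors' deposited table and myoglobin MB -10.03 ± 1.22 (adjusted p 3.69e-14). Of the 24 rows of the skeletal muscle list 16 were called negative and 3 positive, the same counts as when adjusted over the list alone, and the median was -5.58 (-5.51 with rows at 0 at their bound), lower than in every random list. Markers of 3 other cell types also leaned to the negative side, while bile duct markers did not (3 of 6 rows positive and 1 negative). For endothelial and stellate cells 10 of 18 rows were called negative and 0 positive, also when adjusted over the list alone, with collagen COL1A1 at -4.15 ± 0.54 and smooth muscle actin ACTA2 at -3.50 ± 0.50. For leukocytes 8 of 20 rows were negative and 1 positive (8 and 2 adjusted over the list alone), with the actin-bundling LCP1 at -2.67 ± 0.32. For erythrocytes 4 of 9 rows were negative and 0 positive (the same adjusted over the list alone), with the heme enzyme ALAS2 at -1.84 ± 0.49.

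The 10 sardine rows with the largest positive fold change were all at 0 on the negative side. SYNPO2L, a muscle Z-disc gene, was at least 8896-fold higher on the positive side, MFAP4 at least 1842-fold, FAM186A at least 1141-fold, FOXC1 at least 927-fold and the ribosomal gene RPS9 at least 750-fold higher. MFI2, SUV420H2, AMBP, NACA and PROC followed, with bounds from at least 706-fold higher for MFI2 to at least 281-fold for PROC. SYNPO2L, MFAP4, MFI2 and PROC were predicted messenger records and FAM186A and FOXC1 predicted noncoding ones; of predicted messenger records with a mean of at least 10, 87.6% were at 0 on the negative side, against 7.72% of curated records. These bounds hold only if both sides were counted on the same transcripts, which the table does not show. Hepatocyte markers were called positive in 26 of 28 rows and negative in 1, and the acute phase and complement list in 41 of 46 rows and in 0, each with the same counts when adjusted over the list alone. The medians were 5.96 and 2.76, or 2.72 and 2.25 with rows at 0 at their bound, and apolipoprotein APOA4 stood at 2.27 ± 0.22 in the authors' deposited table. Of 25 rows for cholesterol synthesis 16 were called positive and 0 negative (23 and 0 adjusted over the list alone). Their median of 2.63 (2.16 with rows at 0 at their bound) lay at percentile 96.8 of random lists, or at percentile 99.98 for curated records, where 13 of 18 rows were called positive. The phase 2 and antioxidant list had 24 of 43 rows positive and 1 negative (24 and 2 adjusted over the list alone), with the lipid peroxidase GPX4 at 5.09 ± 0.43, and a median of 4.66 that became 0.10 with rows at 0 at their bound. Bile acid genes had 9 of 20 rows positive and 0 negative (12 and 0 adjusted over the list alone), but their median, also 4.66, became 0 with rows at their bound. Glucose metabolism was mixed, with 17 of 36 rows positive and 9 negative (22 and 10 adjusted over the list alone), the gluconeogenic FBP1 at 3.82 ± 0.74 and hexokinase HK1 at -2.72 ± 0.58. Its median of 3.19 became 0 with rows at their bound, and in curated records it was 0.01, or -0.40 at the bound. In all, 9 of the sardine lists were displaced against random lists, 5 to the positive side (phase 2, bile acid, glucose, acute phase and hepatocyte genes) and 4 to the negative side. In curated records glucose metabolism (percentile 94.4) and erythrocyte markers (19.5) no longer were, and at a mean of at least 10 neither were phase 2 genes (89.2) or leukocyte markers (2.81).

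**Figure D1:**
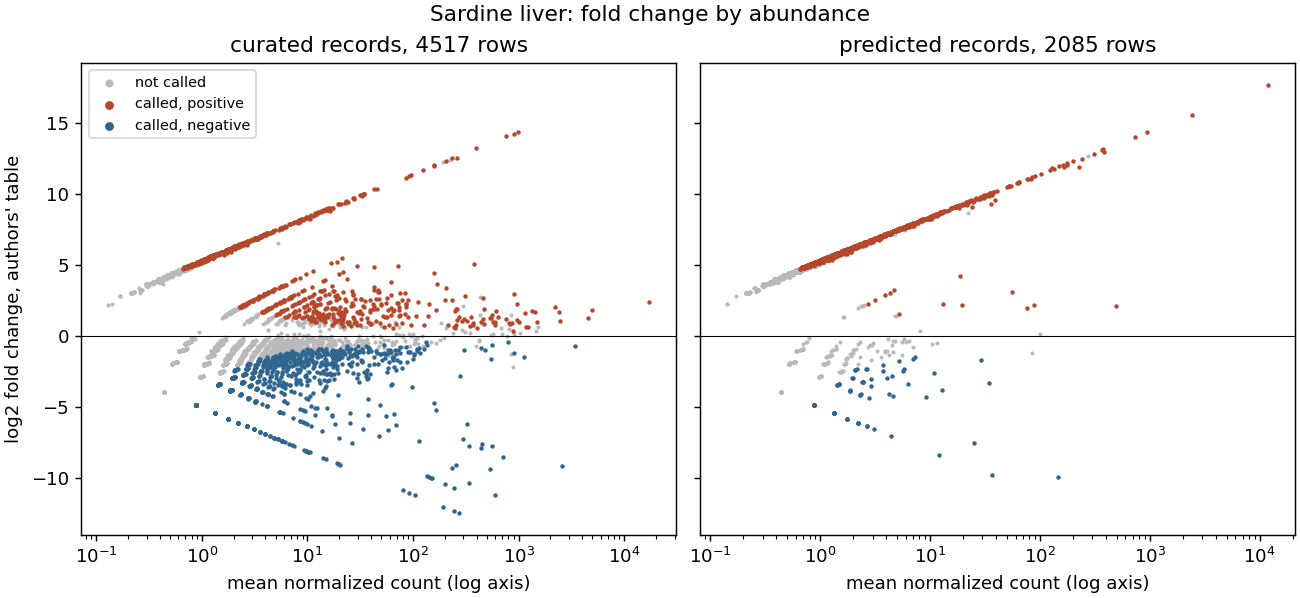
Log2 fold change against mean normalized count for rows of the authors' deposited sardine table, with curated and predicted messenger records in separate panels and called rows in colour. Predicted messenger records were at 0 on the negative side in 82.3% of rows and curated records in 19.7%.

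The hormone genes of the sardine rested on few reads. The dioxin-responsive CYP1A1 had 5 recovered reads on the negative and 4 on the positive side and a fold change of -2.33 ± 0.88 in the authors' deposited table (adjusted p 0.0268). Estrogen receptor ESR2 and IGF1 had 0 negative-side reads and adjusted p of 0.0814 and 0.0869 in the authors' deposited table, and the aromatase CYP19A1 and the egg-envelope genes ZP4 and ZP3 had 1 negative-side read each (0.0877, 0.0877 and 0.583). No fold is given for these 5, none of which had over 6 recovered reads on either side. The hormone-binding protein SHBG was at least 15.1-fold higher on the positive side, and the membrane progesterone receptor components went apart, PGRMC1 at 2.45 ± 0.57 and PGRMC2 at -1.68 ± 0.34. Of the 2010 positive calls 1591 were rows at 0 on the negative side, and curated records alone gave 881 positive and 973 negative calls, rows with reads on both sides 419 and 773. The negative side entered each solved row as a single whole number. Where the positive side had 0 reads, rows with the same number had the same SE, so the authors' SE shows no spread between the 5 fish of that side.

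The second comparison asked the same of the mackerel. The authors' deposited table put the acute-phase pentraxin CRP highest on the positive side at 5.27 ± 0.29 (SE; adjusted p 1.91e-70), with 521 recovered reads against 7 and a ratio of 60.2 (95% interval 29.0 to 150). ZP1, a protein of the egg envelope, was at 3.96 ± 0.26 (adjusted p 1.17e-50) in the authors' deposited table, with 510 reads against 22 and a ratio of 18.8 (12.2 to 30.2). The sterol synthesis enzyme LSS was at 3.52 ± 0.30 (adjusted p 1.71e-28), with 79 reads against 3 and a ratio of 21.3 (7.03 to 105). On the negative side the fatty acid carrier FABP3 was at -3.58 ± 0.25 (adjusted p 2.38e-42), with 55 reads against 615, and the lipogenic regulator MID1IP1 at -2.58 ± 0.25, with 470 against 2477. The authors' DESeq2 test called 1570 of 6319 rows with an adjusted p, 890 positive and 680 negative, at a median of 0.04 over all rows.

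The other 7 mackerel rows with the largest positive fold changes included metabolic enzymes. BRF1, a subunit of an RNA polymerase III factor, had 58 reads against 0 and was at least 15.6-fold higher on the positive side. The bile acid enzyme CYP8B1 was at least 4.85-fold and the small GTPase ARL2 at least 4.58-fold higher. P11 had a ratio of 10.5 (5.70 to 21.5), apolipoprotein APOA4 14.6 (3.75 to 125), and the cytochrome P450 CYP3A5 and the amidase NAAA 21.0 each (3.45 to 862) from 26 reads against 1. On the negative side the protease CTSE had 1 read against 49 and a ratio of 0.0165 (0.00041 to 0.0964), and the muscle attachment gene NRAP had 3 against 45 and 0.0539 (0.0107 to 0.168). The transporter-family ATPase ABCF2 had 20 reads against 165, the calcium sensor S100A1 1 against 23 (ratio 0.0352, 0.000854 to 0.217), GFRA1 1 against 19 (0.0426, 0.00102 to 0.268) and COX11 21 against 112. The calcium channel ITPR3 was at least 6.18-fold and FGD6 at least 4.53-fold lower on the positive side, where both had 0 reads.

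**Figure D2:**
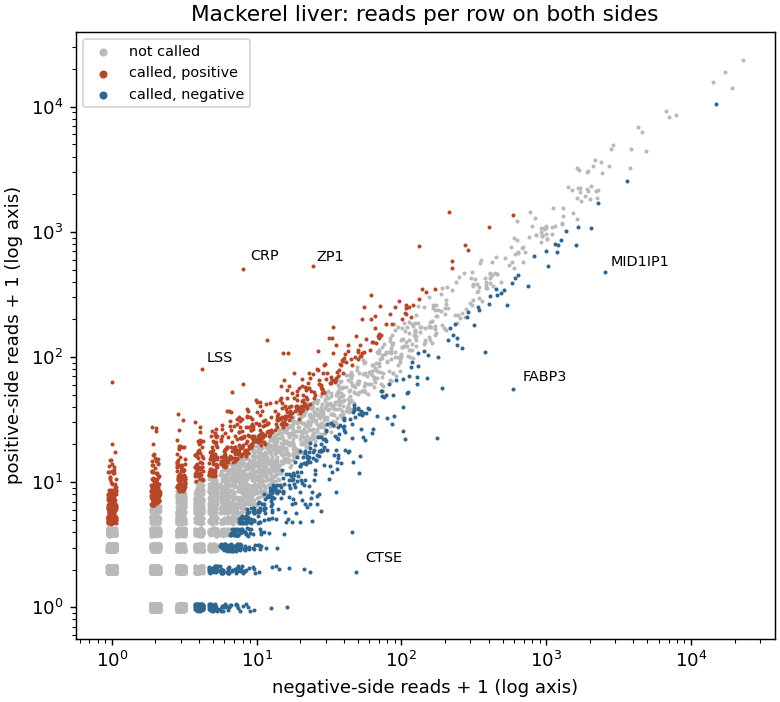
Recovered reads per mackerel row on the positive side against the negative side, on log axes with points jittered, and the rows called in the authors' deposited table in colour. CRP (521 against 7 reads) and ZP1 (510 against 22) lie toward the positive side, FABP3 (55 against 615) toward the negative side.

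Cholesterol synthesis was the most displaced mackerel list, with 16 of 24 rows called positive and 1 negative (17 and 2 adjusted over the list alone) and a median of 1.3 (1.11 with rows at 0 at their bound), above every random list. The exact test of the recovered reads called 6 of these rows positive and 0 negative. Beside LSS, the isomerase EBP stood at 2.42 ± 0.25 with 60 reads against 7, phosphomevalonate kinase PMVK at 2.26 ± 0.24 with 102 against 15, and ACAT2 at 1.77 ± 0.25 with 33 against 6. The single negative row was SCAP, the escort of sterol-regulated transcription factors, a gene that was named after its value was seen. Fatty acid oxidation had 10 of 39 rows positive and 0 negative (11 and 0 adjusted over the list alone), including ECHS1 at 1.33 ± 0.23 with 70 reads against 21, and a median of 0.29 (0.09 at the bound), at percentile 99.99; the exact test called 3 positive and 0 negative. The proteasome had 9 of 41 rows positive and 2 negative (the same adjusted over the list alone) and a median of 0.28 (0.12 at the bound) at percentile 98.5, or 86.4 in rows of at least 10 reads, and the exact test called 5 and 0.

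Acute phase and complement genes leaned to the negative side in mackerel although CRP did not. Of 65 rows 18 were called negative and 6 positive (22 and 7 adjusted over the list alone), with a median of -0.26 at percentile 0.44, and 21 negative and 8 positive by the exact test. Complement C3 stood at -2.24 ± 0.24 with 7 reads against 35, while a second CRP row stood at 2.36 ± 0.25 with 1458 against 212. Ribosomal protein genes had 14 of 84 rows negative and 2 positive (12 and 2 adjusted over the list alone) and a median of -0.24 (-0.22 at the bound) at percentile 0.35, or 11.3 in rows of at least 10 reads, with RPLP1 at -1.31 ± 0.25 and 350 reads against 736. The exact test called 40 ribosomal rows negative and 8 positive. Endothelial and stellate markers had 5 of 19 rows negative and 1 positive, the same adjusted over the list alone. Their median of -0.70 lay at percentile 0.33 and is the fold change of a row with 0 reads against 1. With rows at their bound it was -0.24, which was also the median of random lists without that bound. The list held 31 reads against 58, with collagen COL1A2 at 6 against 20, and the exact test called 1 negative and 0 positive. Hepatocyte markers were split, 9 of 34 rows positive and 10 negative (10 and 11 adjusted over the list alone), with the peroxisomal AGXT at 2.02 ± 0.24 and apolipoprotein APOB at -1.30 ± 0.22, and 5 positive and 9 negative by the exact test.

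**Figure D3:**
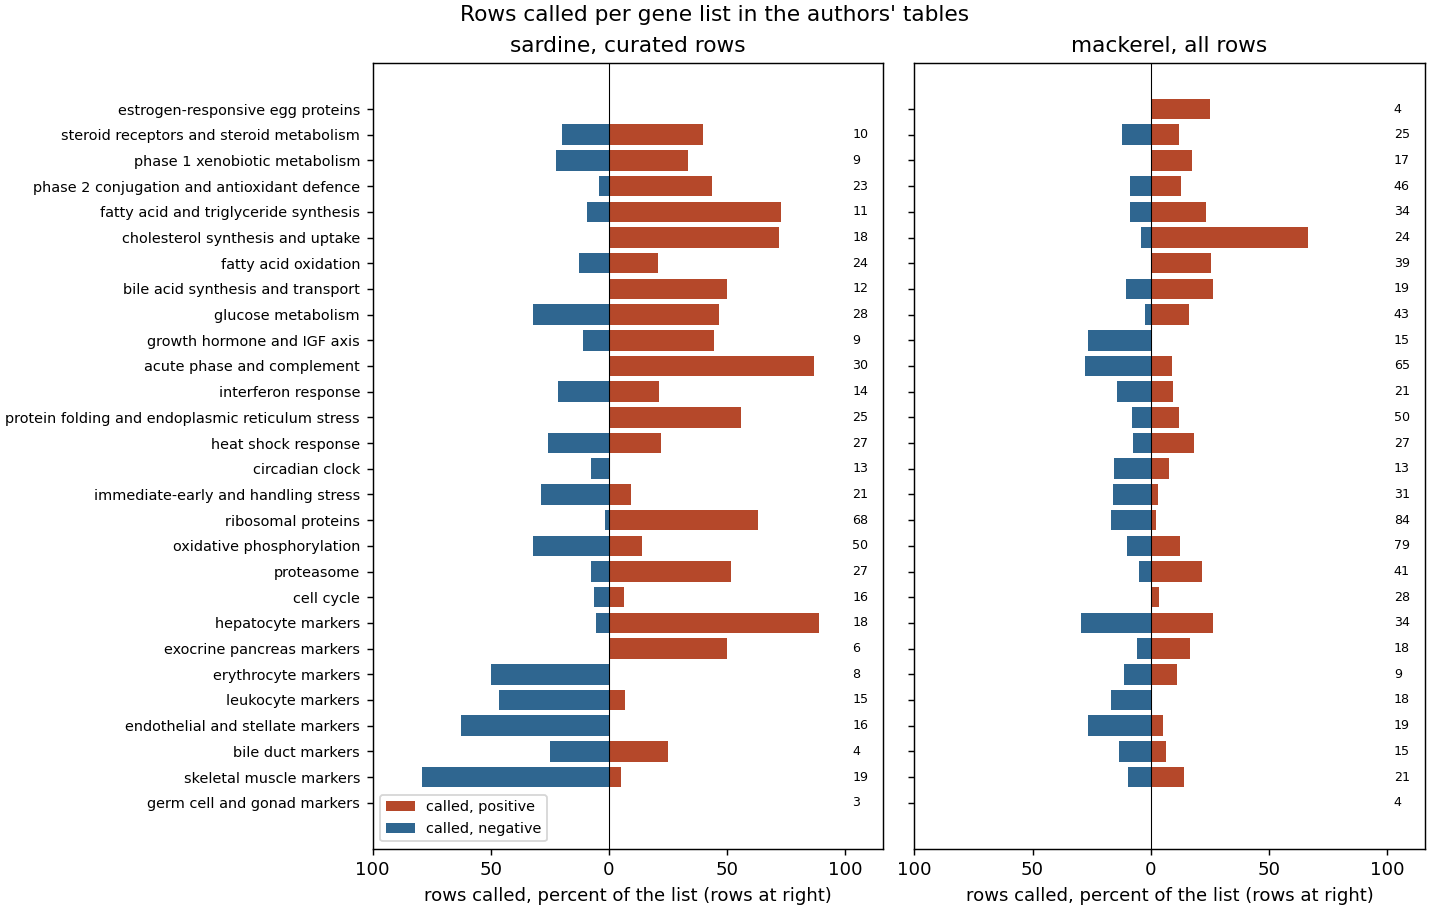
Percentage of the rows of each gene list called on the positive and on the negative side, in sardine (curated records) and mackerel (all rows), with row counts at the right. Cholesterol synthesis has 13 of 18 sardine rows and 16 of 24 mackerel rows on the positive side.

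Few reads were present for the other egg genes of the mackerel and for its hormone genes chosen for naming beforehand, IGF1 apart. ESR2 had 6 reads against 1 (adjusted p 0.0375 in the authors' deposited table, ratio 4.85, 0.589 to 223) and ESR1 1 against 3 (adjusted p 0.086). IGF1 had 66 against 56 and a ratio of 0.953 (0.658 to 1.39), CYP1A1 4 against 2, and ZP4 and the better covered ZP3 row 1 read on each side. The steroid list had 3 of 25 rows called positive and 3 negative. Its better covered SHBG and PGRMC1 rows were negative, where both genes were positive in sardine. In the authors' deposited table SHBG was at -0.88 ± 0.24 (adjusted p 0.0026) and PGRMC1 at -0.83 ± 0.22 (adjusted p 0.0019). An exact binomial test of the recovered reads called 348 rows, 173 positive and 175 negative, of which 253 were also called in the authors' deposited table. Every one of the 358 pairs of read numbers shared by at least 2 rows had a single fold change and SE, so the authors' adjusted p holds no spread between fish on either side, and 578 of the 1570 calls rested on fewer than 10 reads.

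The comparison of the species asked whether the responses are alike. The sterol synthesis genes LSS and IDI1 were called positive in both, LSS at 3.09 in sardine and 3.52 in mackerel and IDI1 at 2.54 and 1.5 in the authors' deposited tables. The amino acid enzyme TAT was positive in both (4.50 and 1.59), and myoglobin MB (-10.03 and -1.74), collagen COL1A2 (-3.07 and -1.66) and keratin KRT19 (-3.08 and -1.78) were negative in both. MYEF2 (-2.65 and 2.41), HNRNPA1 (-1.06 and 1.52) and PABPC4 (-5.21 and 1.23) were negative in sardine and positive in mackerel, and A2M, at 0 on the sardine negative side, was -1.60 in mackerel.

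**Figure D4:**
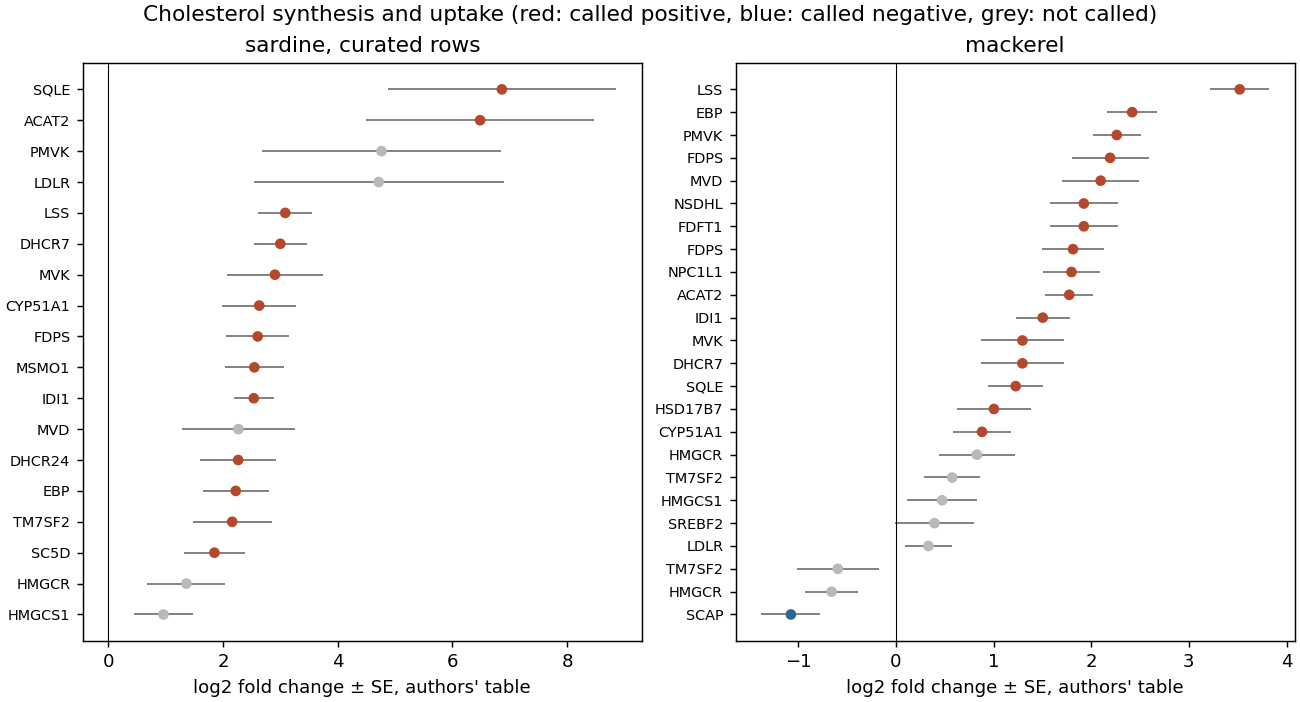
Log2 fold change with its SE for rows of the cholesterol synthesis list in the authors' deposited tables, curated records only in sardine and all rows in mackerel. LSS is at 3.09 in sardine and 3.52 in mackerel.

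Across 3449 shared symbols Pearson's r of the fold changes was 0.0449 and Spearman's rho 0.0566, and random pairings gave r from -0.0431 to 0.0611; this is across genes, which are not independent replicates. In symbols with reads on both sides in both species r was 0.137, outside the -0.0820 to 0.0797 of their random pairings, and in curated sardine records it was 0.0646, just outside -0.0605 to 0.0610. Of 2750 symbols with an adjusted p in both species, 424 were called in both: 188 positive in both (159.96 if independent), 39 negative in both (48.9), 146 positive in sardine and negative in mackerel (110.9), and 51 the other way (70.6). Whether a gene's fold change differed between the species was not tested, and the side that stands for exposure is unknown in each table.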

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

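The test of single libraries for a distant value was planned, and the items it covered were settled only after the counts had been recovered. SLC51A, a bile acid exporter, had 18 recovered reads in 1 of the 5 positive-side sardine libraries and 1 to 7 in the others, and the gap to the nearest library was 0.784 of the whole range after scaling. It was 1 of 13 items tested, and chance alone puts about 1 in 20 past the critical value.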

How the results depend on the processing

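No displaced list crossed the middle of its random lists. The median of the sardine glucose list (3.19) was 0.01 in curated records and turned to -0.40 there with rows at 0 at their bound. Sardine calls (3071) numbered 4779 at an adjusted p under 0.1, as a looser threshold must give, and among alternatives added after seeing the data 1854 in curated records, 1192 in rows with reads on both sides and 756 at a mean of at least 10, each a subset of the rows. Recomputed adjustment (3149), a fold of at least 2 (2990), a single row per symbol (2435) and leaving out the muscle lists (3018) stayed within 1.5 times. Mackerel calls (1570) numbered 1003 at a fold of at least 2 and, in added alternatives, 992 at 10 or more reads and 348 by the exact test; 2211 at an adjusted p under 0.1 (1088 positive and 1123 negative, against 890 and 680), 1349 recomputed and 1358 per symbol were within 1.5 times. Of the 111 called and named mackerel rows 53 passed the exact test and 58 did not. Displaced sardine lists (9) numbered 4 at a mean of at least 10 and 12 in curated records. In curated records steroid, cholesterol, growth hormone, protein folding and ribosomal lists were gained and glucose (94.4) and erythrocyte (19.5) lists lost. The curated steroid (1.94) and growth hormone (4.45) medians became 0 with rows at 0 at their bound. Those of the cholesterol, protein folding and ribosomal lists stayed above 0. At a mean of at least 10 phase 2 (89.2), glucose (83.8), erythrocyte (7.64) and leukocyte (2.81) lists were lost and bile acids had too few rows. Mackerel lists (6) numbered 5 at 10 or more reads, with lipid synthesis (percentile 99.8) and bile acids (97.8) gained, ribosomal (11.3) and proteasome (86.4) lists lost, and endothelial markers with too few rows. The cause was otherwise not tested. Without paralogues matched by a final letter, also added after seeing the data, 9 and 6 were displaced, and leukocyte calls became 0 positive and 7 negative in sardine and 0 and 1 in mackerel. Between species r (0.0449) was 0.137 with reads on both sides, cause not tested, 0.0646 in curated records, and -0.0130 and 0.0477 in the other settings. Not run for want of values per library were the other normalizations, edgeR, DESeq2 and limma-voom fits, count filters, summed rows, pseudocounts, camera and fry, marker levels per library, the species interaction and leaving out each fish. Depth limits the mackerel, where 6611 of 9191 rows had fewer than 10 reads.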

Other observations

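The tests in this part of heart muscle, of transcript sets and of single whole numbers were chosen after the results were seen; the gene lists of the next paragraphs were fixed beforehand, apart from the cardiac and fast skeletal lists.

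Genes for protein folding and the endoplasmic reticulum had 19 of 32 sardine rows called positive and 0 negative (22 and 0 adjusted over the list alone), with the translocon subunit SSR3 at 2.32 ± 0.33 and the signal peptidase SEC11A at 3.44 ± 0.54 in the authors' deposited table. Ribosomal protein genes had 48 of 73 sardine rows positive and 1 negative (the same adjusted over the list alone), with RPS2 at 1.71 ± 0.13. Oxidative phosphorylation had 22 positive and 16 negative of 68 (25 and 16 adjusted over the list alone), with ATP5C1 at -1.80 ± 0.21. Transcription factors of the immediate-early list were among the negative calls of the sardine, KLF6 at -2.13 ± 0.38 and a KLF2 row at -3.43 ± 0.73, and the clock repressor BHLHE40 was at -3.01 ± 0.33 in the authors' deposited table. In counts of positive and negative calls, the sardine had 4 and 2 of 10 rows for steroid receptors, 3 and 3 of 10 for phase 1 metabolism, and 14 and 2 of 21 for lipid synthesis. It had 10 and 3 of 31 for fatty acid oxidation, 6 and 1 of 11 for the growth hormone axis, and 11 and 3 of 33 for interferon response. It had 9 and 7 of 31 for heat shock, 0 and 1 of 13 for the clock, 5 and 6 of 27 for immediate-early genes, and 19 and 2 of 32 for the proteasome. Counts were 1 and 1 of 16 for the cell cycle, 4 and 0 of 9 for exocrine pancreas, 3 and 1 of 6 for bile duct, and 0 and 0 of 3 for gonad markers. Adjusted over the list alone the counts became 5 and 3 for phase 1 metabolism, 15 and 2 for lipid synthesis, 13 and 3 for interferon response, 10 and 7 for heat shock, 5 and 8 for immediate-early genes and 22 and 2 for the proteasome, and did not change in the others of these lists. In 4 of these sardine lists positive calls no longer outnumbered negative ones in curated records alone, an alternative chosen after seeing the data. The counts were 7 and 16 of 50 for oxidative phosphorylation, 6 and 7 of 27 for heat shock, 3 and 3 of 14 for interferon response and 1 and 1 of 4 for bile duct. For fatty acid oxidation they were 5 and 3 of 24, with a median that went from 0.63 to -0.53. Rows with a mean of at least 10 gave 7 and 14 of 29 for oxidative phosphorylation, 5 and 6 of 14 for heat shock, 1 and 2 of 4 for interferon response, 1 and 2 of 8 for fatty acid oxidation and 2 and 0 of 3 for bile duct. The positive cell cycle call was a row of TOP2B, a paralogue of the listed gene. The egg proteins had too few rows, 2.

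In mackerel the interferon-inducible IFI27 stood at -2.17 ± 0.24 with 24 reads against 98, the kinase PIM1 at -2.28 ± 0.24 with 10 against 48, and the transcription factor JUNB at -1.64 ± 0.23 with 30 against 82. The superoxide dismutase SOD2 stood at 1.73 ± 0.23 with 44 against 9 in the authors' deposited table. In counts of positive and negative calls, mackerel had 1 and 0 of 4 rows for egg proteins, 3 and 3 of 25 for steroid receptors, 3 and 0 of 17 for phase 1 and 6 and 4 of 46 for phase 2 metabolism. It had 8 and 3 of 34 for lipid synthesis, 5 and 2 of 19 for bile acids, 7 and 1 of 43 for glucose metabolism, and 0 and 4 of 15 for the growth hormone axis. It had 2 and 3 of 21 for interferon response, 6 and 4 of 50 for protein folding, 5 and 2 of 27 for heat shock, 1 and 2 of 13 for the clock, 1 and 5 of 31 for immediate-early genes, 10 and 8 of 79 for oxidative phosphorylation, and 1 and 0 of 28 for the cell cycle. Cell type markers gave 3 and 1 of 18 for exocrine pancreas, 1 and 1 of 9 for erythrocytes, 0 and 3 of 18 for leukocytes, 1 and 2 of 15 for bile duct, 3 and 2 of 21 for skeletal muscle, and 0 and 0 of 4 for gonad. Adjusted over the list alone the counts became 2 and 0 for phase 1 metabolism, 8 and 4 for lipid synthesis, 6 and 4 for bile acids, 4 and 0 for glucose metabolism, 0 and 5 for the growth hormone axis, 6 and 2 for heat shock and 1 and 5 for bile duct, and did not change in the others of these lists. Of the 3 leukocyte calls 2 were rows of ARPC1A, a paralogue of the listed gene. By the exact test, chosen after seeing the data, positive and negative calls were 8 and 1 for protein folding, 3 and 0 for lipid synthesis, 2 and 0 each for bile acids and heat shock, 2 and 1 for glucose metabolism, 2 and 2 for oxidative phosphorylation and 1 and 2 for immediate-early genes. They were 1 and 0 each for egg proteins, phase 1 and phase 2 metabolism, bile duct and skeletal muscle. They were 0 and 1 each for steroid receptors, interferon response, exocrine pancreas and leukocytes. The growth hormone axis, the clock, the cell cycle, erythrocytes and gonad had 0 calls by that test. The added lists gave 1 and 2 of 26 for cardiac and 1 and 1 of 12 for fast skeletal muscle (0 and 1, and 1 and 0, by the exact test), where the sardine had 2 and 9 of 17 for fast skeletal muscle.

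Heart muscle genes lay mostly on the sardine negative side: the cardiac list had 29 of 43 rows called negative and 3 positive and took 5.73% of that side's reads, and on the positive side 10.98% of normalized counts, 0.0292% without the row SYNPO2L. Fast skeletal muscle as the source of the cardiac reads was argued against by 201 negative-side reads of its list against 7190, although that list was itself displaced to the negative side (median -2.74). Heart muscle RNA in the negative-side count is a candidate explanation, with a ratio of 35.8 between the lists, an estimated 1354 reads for TNNT2 and 760 for MYH6, and 20.1% of the list's reads in ACTC1, which the skeletal muscle list also holds. Slow skeletal muscle was not tested and stays open, since the skeletal muscle list held 12152 negative-side reads, more than the cardiac list, and TPM3, TNNI1, TNNC1, MYH7 and MB are also genes of slow fibres. A response of the liver to exposure cannot be told apart from these, because side and group coincide in the sardine, and percentile 28.6 in mackerel, where 16 of its symbols had a row against 26 in sardine, excludes nothing in another species.

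Predicted transcripts were at 0 on the sardine negative side far more often than curated ones. A response to exposure as the only source of that split was argued against but not excluded. Among rows with a mean of at least 100, 21 of 23 predicted messenger records and 12 of 161 curated records were at 0, a ratio of shares of 12.25. The 2 kinds of record hold different genes, so a part played by exposure cannot be ruled out. Counting the 2 sides against different sets of transcripts may account for the split, which was a ratio of 11.3 at a mean of at least 10 (87.6% against 7.72%). Both ratios only describe the split itself, so neither is a separate test of that explanation. Calls on rows at 0 on the negative side, 1591 of the 2010 positive ones, carry this open question.

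Each group entered the mackerel table as 1 whole number per row, and so did the sardine negative side. In mackerel separate counts for 5 fish were excluded, since 0 of the 358 shared pairs had more than 1 fold change or SE. In sardine they were argued against by 773 rows with 0 positive-side reads. These held 11 negative-side numbers, and 0 of the 11 had more than 1 SE. Sardine fold changes lay a median of -0.00237 log2 from those of a negative side in 5 columns. That check cannot tell 1 number entered 5 times from 5 separate counts, because both give the same negative-side total. For mackerel a candidate explanation is 1 count per side entered in 5 columns with 0 to 4 added. It gives a constant of 1.64 times the sum of the steps where 1.63 was observed. Adding 1 to 5 in 5 columns gives 2.58, 0 to 3 in 1 column fewer 1.24, and 0 to 5 in 1 column more 2.00. The nearest other setting tried, 1 to 3 in fewer columns, gives 1.82. The steps under 0 to 4 were 0.452 and 0.565 where 0.455 and 0.563 were observed, so the construction was not matched exactly. No biological explanation of these whole numbers was tested.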
